A study of Mus musculus with 4 samples.

How the data were processed

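Interstitial (non-cardiomyocyte) cells of mouse hearts were measured by droplet single-cell RNA sequencing 1 month after stroke or a control condition, in 4 samples, 2 from control and 2 from stroke animals. The strain, named Ccr2creERT2-Ai14 in the labels, pairs an inducible Cre recombinase under the Ccr2 gene with a Cre-dependent tdTomato reporter. Per the labels' protocols, hearts were cut up, digested with enzymes for 30 min, strained to hold back cardiomyocytes, treated to lyse red blood cells and depleted of dead cells with magnetic beads. Live nucleated cells were then sorted on a DNA dye, and libraries were made with the 10x Genomics 3′ v3.1 chemistry at a target of 20000 reads per cell. Each of these steps can set how many cells of a type were recovered. The digestion can also switch on early response genes before the cells are lysed, and red cell lysis and sorting remove erythroid cells.

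The authors deposited 1 table of counts, in which each value is the whole number of unique molecular identifiers (UMIs, 1 per captured RNA molecule) of a gene in a cell barcode. It holds 32286 features and 39731 barcodes, and the tdTomato sequence is 1 of the features. Per the file headers and the submitters' processing notes the counts were made with Cell Ranger 7.1.0, on build mm10 of the mouse genome. How the libraries were joined, and whether their depths were equalised in that step, is not given in the sources used here. Barcodes carry a suffix from 1 to 4, which was read as 4 libraries. No label ties a suffix to a sample, so the libraries were left without a group. Stroke and control were therefore not compared, and the planned tests between them were not run. With 2 samples per group the planned exact permutation test of cell shares could have reached a two-sided p of 0.333 at the lowest. The joined table was treated as 1 sample, and the design ran no test where cells are not tied to samples. No p-value, standard error or mean with SD is therefore given, also for contrasts within libraries such as that of macrophage subsets. In their place, each library's value or the range over the 4 libraries is given for some shares, lists and genes. Other levels and ratios are pooled over the libraries.

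Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 15% mitochondrial UMIs. Doublets (droplets with 2 cells) were scored in each library with Scrublet as implemented in scanpy 1.11.5, and barcodes over the threshold were removed. In library 3 the automatic threshold of 0.522 marked 1 of 8813 barcodes (0.0113%), under the 0.5% taken as the least for a working threshold, and the median threshold of the other libraries, 0.188, was used there after the scores had been seen. Counts were scaled to 10000 per cell and log-transformed (log of 1 plus the value). The 2000 most variable genes seen in at least 20 cells were chosen by dispersion in 20 bins of mean expression, scaled, and limited to 10 SD. Every gene of the functional lists, the reporter, and mitochondrial, ribosomal and sex-linked genes, 432 in all, were left out first, so that the clusters were not built on the genes whose levels are reported. Clusters came from 30 principal components, 15 neighbours with shared-neighbour weights, and the Leiden method at resolution 1 (leidenalg 0.10.2 and igraph 0.11.9, 5 iterations, seed 0), without correction between libraries.

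Clusters were named from 24 marker lists with 142 genes. A cluster took the class with the highest mean log2 fold over all other cells, computed with 20 CPM added on both sides. It needed at least 3 markers at 2-fold or above and at least 20 cells. It stayed unnamed where markers of another class outnumbered its own among its 10 leading genes (of those at 100 CPM or more), or where its depth was under 1/3 of its libraries' medians with no marker leading. Clusters that carried markers of unrelated classes were divided once more by the same steps, which was decided after the first clusters had been seen. All names are written as X-like, since they rest on RNA alone. Classes with at least 50 cells entered the comparison of gene levels.

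For each class, UMIs were summed over its cells and divided by the class's total UMIs, on the CPM scale in common use for read counts. Intervals are 95% intervals, exact Poisson for a CPM, exact binomial (Clopper-Pearson) for a share of cells, and exact conditional binomial for a ratio of CPM values. They cover counting error only, not the spread between animals. A count of 0 was taken to allow up to 3 UMIs. The 18 functional lists hold 239 genes, of which 237 were among the features. Mx1 and Wisp2 were not matched by symbol. A list's level is the sum of its members' CPM, so that its most abundant members decide it.

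Macrophages were compared within the macrophage-like cluster richest in C1q transcripts. It was divided into sub-clusters without functional-list genes and without markers of non-myeloid classes, and sub-clusters enriched in at least 3 markers of a non-myeloid class or under 0.5 of the highest C1q level were left out. Erythroid markers were exempt, so that sub-clusters led by haemoglobin genes stayed in. Those with at least 0.5 of the highest summed CPM of Lyve1, Timd4 and Folr2 formed the Lyve1-high side and all others the Lyve1-low side. How the cluster was divided was decided after the first clusters had been seen. A gene was called higher or lower where its CPM ratio was at least 2 over all cells and at least 1.5 in the same direction in every library, with at least 50 UMIs over both sides. The 3 genes that define the sides and the reporter were not counted. This size rule was tested on simulated counts for the macrophage comparison, drawn from the real mean levels of 8187 genes. It called 65.7% of genes made 2.5-fold different, 85.1% of those made 4-fold different and 95.5% of those made 8-fold different, and called 7 of 7987 genes left equal. The simulated counts held Poisson error only, at the same rate in every library, without spread between cells or choice of sides by clustering. These rates hold for such counts only.

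The text names genes by a rule. For each functional list it takes up to 4 members with the highest CPM in the class where the list is highest, and any member whose own highest class differs from the list's. For the macrophage comparison it takes up to 15 genes higher and 15 lower by ratio. Il1b, Ccr2, Mmp9, Col1a1, Col3a1, Postn and the reporter are always named. Some genes that the rule takes are not reported here, though list levels and counts include them. Cell filters, lists, markers, the size rule and the named-gene rule were fixed before the data were examined, as were the alternatives except those named in the closing part as added later. Alternatives were a stricter cell filter (1000 UMIs and 10% mitochondrial UMIs, for cell classes only), doublets kept, Leiden resolutions of 0.5 and 2, a mean over cells of each cell's CPM, cells thinned to 1000 UMIs, and leaving out each library. Coordinates are from the GENCODE M21 annotation of the same genome build, in which 379 of 379 listed genes were matched by identifier. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9. Counts of near-identical genes (the Oas and Ifit families, H2 genes, Hspa1a and Hspa1b, Hba-a1 and Hba-a2, and Ccl2, Ccl7 and Ccl12) can be split between copies, and such levels are less certain than those of single genes.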

Results

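Interstitial cells of the mouse heart were profiled 1 month after stroke or a control condition, a setting in which the study's title asks about innate immune memory. The samples are 2 control and 2 stroke hearts. The deposited counts join all cells in 1 table whose 4 libraries are numbered but not tied to a sample, so no value below is assigned to stroke or control. What the table can show is which cell types were recovered, which of them carried inflammatory, matrix and repair transcripts, how macrophage subsets of the heart differed, and how far the 4 libraries lay apart.

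The libraries held 44156588, 45834980, 31955157 and 37067428 UMIs in 9888, 10202, 9168 and 10473 barcodes. After filtering and doublet removal, 9394, 9501, 8600 and 9970 cells were analysed, 37465 in all. The median was 3484, 3412, 2718.5 and 2568 UMIs per cell in libraries 1 to 4. The 821 barcodes that failed the filter and the 1445 removed as doublets enter no value of the comparisons.

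Endothelial-like cells were the largest population, with 22740 of 37465 cells (60.7%, 95% interval 60.2 to 61.2). They comprised capillary-like or general endothelial cells (42.8%), arterial-like cells (9.68%), endocardial-like cells (7.83%), which line the chambers, and lymphatic-like cells (0.400%). No cell was named venous-like in the main setting, against 309 with the stricter cell filter and 304 at Leiden resolution 2. Fibroblast-like cells, the main matrix producers of the heart, made up 21.7% (21.3 to 22.2). Immune-like cells made up 12.98% (12.6 to 13.3), led over all libraries together by B cell-like cells (4.11%) and macrophage-like cells (3.28%). In libraries 1 and 3 macrophage-like cells outnumbered B cell-like cells (153 against 103 and 648 against 234). Smaller immune classes were T cell-like (1.90%), non-classical monocyte-like (1.09%), neutrophil-like (1.06%), NK cell-like (0.614%), monocyte-like (0.320%), group 2 innate lymphoid (ILC2)-like (0.312%) and dendritic-like cells (0.243%). Pericyte-like (1.29%), epicardial-like (0.817%), smooth muscle-like (0.339%) and Schwann-like cells (0.307%) completed the 18 classes with at least 50 cells. Epicardial-like is short here for an epicardial or mesothelial class, as its markers, such as Msln and Upk3b, were listed for both together. Cardiomyocyte-like, erythroid-like and mast cell-like clusters held 33, 27 and 20 cells, and 1.66% of cells lay in unnamed clusters. Straining, red cell lysis and sorting can each set these shares. With the stricter cell filter the fibroblast-like share was 13.4%, where 19.2% of cells were in unnamed clusters, and with doublets kept and at Leiden resolution 2 the erythroid-like share was 5.18% and 2.53% in place of 0.0721%. Of those 2014 and 946 cells, 1973 and 923 were endothelial-like in the main setting, and the endothelial-like share there was 54.2% and 56.0%.

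Shares of the main classes differed between libraries by more than their counting intervals, whereas the intervals of the lowest and highest library overlapped for ILC2-like and dendritic-like cells. Fibroblast-like cells ranged from 7.74% in library 3 to 35.2% in library 1 (median 21.4%), and endothelial-like cells from 50.7% in library 1 to 72.2% in library 3 (median 60.3%). Macrophage-like cells took 7.53% (6.99 to 8.11) of library 3 and 1.56% to 2.86% of the others. B cell-like cells took 9.81% (9.22 to 10.4) of library 2 and 1.10% to 2.72% of the others. Neutrophil-like cells ranged from 0.287% to 1.62% (median 1.19%).

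**Figure D1:**
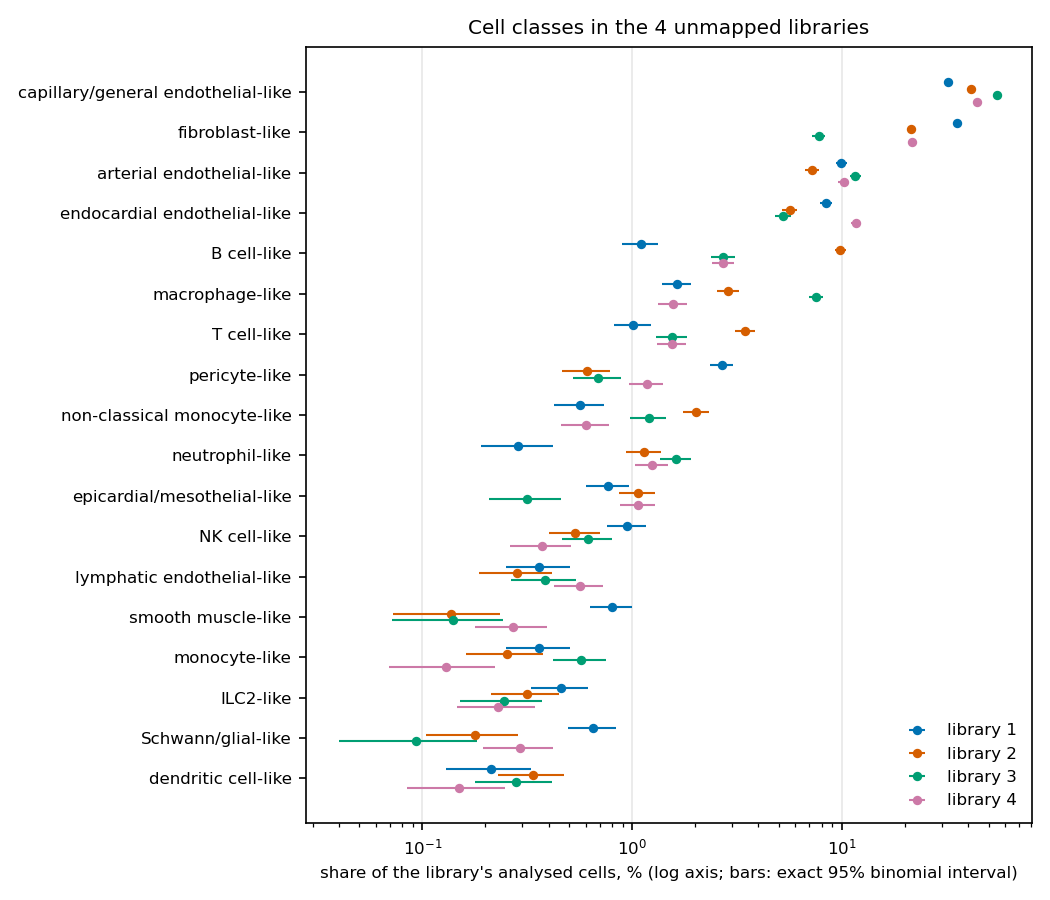
Share of each library's analysed cells in percent (log axis) for the 18 cell classes with at least 50 cells; points are the 4 unmapped libraries and bars exact 95% binomial intervals. Fibroblast-like cells spread from 7.74% to 35.2% and macrophage-like cells from 1.56% to 7.53%.

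Which cells carry the signals of innate immunity was asked next, by summing each functional list over the cells of a class. Neutrophil-like cells held the IL-1 and inflammasome list at 17533 CPM (17296 to 17773), 8.33 times the level in non-classical monocyte-like cells (2104 CPM). Il1b, the secreted cytokine, gave 66.9% of it, followed by the decoy receptor Il1r2 (3675 CPM), the inflammasome sensor Nlrp3 (778 CPM) and the receptor subunit Il1rap (632 CPM). Of the 15 members, 7 were highest in neutrophil-like cells. Among the 8 others, the signalling receptor Il1r1 peaked in pericyte-like cells (144 CPM), Il18 in epicardial-like cells (172 CPM), Il1a in macrophage-like cells (34.5 CPM, and 13.2 CPM without cluster 29, a cluster of 112 of their 1229 cells), and the adaptor Pycard and the pore former Gsdmd in monocyte-like cells (316 and 84.5 CPM). Among classes the TNF and NF-kB list was also highest in neutrophil-like cells (10034 CPM). There the chemokine Cxcl2 stood at 5232 CPM, Nfkbia at 1354, Nfkbiz at 1089 and Birc3 at 477. Cluster 29 alone held the list at 15406 CPM, above that level, against 5888 CPM over all macrophage-like cells. Tnf itself (193 CPM), Il6 (108 CPM) and Ier3 (616 CPM) peaked in macrophage-like cells. Cluster 29 held 94.5% of the Il6 and 58.8% of the Ier3 UMIs of these cells, and without it Il6 was highest in monocyte-like cells (16.5 CPM), Ier3 in neutrophil-like cells (372 CPM) and Tnf still in macrophage-like cells (198 CPM). Other peaks were those of Nfkb1 (2219 CPM) and Tnfaip3 (863 CPM) in ILC2-like cells and Icam1 (221 CPM) in dendritic-like cells, among 9 members that peaked elsewhere.

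Genes that guide monocytes into tissue were spread over many cell types. The recruitment list was highest in neutrophil-like cells (3371 CPM, 1.16 times macrophage-like cells), mainly through Ccl6 (2009.8 CPM), with Ccl4 at 218 and Cxcr4 at 177 CPM, but 13 of 16 members peaked elsewhere. Cxcl12 reached 2348 CPM (2317 to 2380.4) in arterial-like endothelial cells, which also had the most Cx3cl1 (43.4 CPM). Ccl12, Ccl2 and Ccl7, ligands of CCR2, peaked in macrophage-like cells at 314, 205 and 114 CPM. Cx3cr1 peaked in non-classical monocyte-like cells (538 CPM), Ccl9 in monocyte-like cells (340.1 CPM), Ccl4 in NK cell-like cells (1178 CPM) and the growth factor Csf1 in epicardial-like cells (179 CPM).

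The interferon response was not tied to a single cell type. Monocyte-like and neutrophil-like cells held it at close levels (3779.8 and 3766 CPM), ahead of fibroblast-like (2736 CPM) and macrophage-like cells (2690.3 CPM, and 3093 CPM without cluster 29). The order of the first pair turned when cells were weighted equally or thinned to 1000 UMIs. In monocyte-like cells Ifi27l2a (2534 CPM), Bst2 (274) and Irf7 (178) were among the highest members. Isg15 (888 CPM), Rsad2 (409), Oasl2 (351), Ifit1 (187) and Ifit3 (184) peaked in neutrophil-like cells, Bst2 (561 CPM), Ifit2 (156), Ifi44 (107) and Oas2 (87.8) in arterial-like cells, and the T cell attractant Cxcl9 in capillary-like cells (124 CPM). Between libraries the list ranged from 1744 to 6511 CPM in neutrophil-like cells (median 2805). Antigen presentation by MHC class II was highest in dendritic-like cells (39717 CPM), 2.47 times B cell-like cells (16056 CPM), with macrophage-like cells at 15788 CPM. Without cluster 29, which had 202 CPM, macrophage-like cells stood at 19091.5 CPM and above B cell-like cells. In dendritic-like cells the invariant chain Cd74 reached 17656 CPM, H2-Ab1 7145, H2-Eb1 6836 and H2-Aa 6386. Of the 8 members 7 peaked in dendritic-like cells, the exception being H2-Oa in B cell-like cells (138 CPM).

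Macrophage-like cells led the resident macrophage list (7061 CPM, 3.76 times the next class) with Pf4 at 2188, F13a1 at 1578, the mannose receptor Mrc1 at 1186 and Cbr2 at 401 CPM. The 3 members highest elsewhere were Lyve1 (lymphatic-like cells, 1299 CPM), Igf1 (fibroblast-like cells, 256 CPM) and Gas6 (endocardial-like cells, 370.4 CPM). They also led the efferocytosis and complement list (14479 CPM), of which the lipid carrier Apoe gave 79.0% (11434 CPM), with Lgals3 at 543 and Cd36 at 363 CPM. Of the 10 members that peaked elsewhere, the fatty acid receptor Cd36 reached 3683 CPM in capillary-like cells, complement C3 2503 in epicardial-like cells, Lgals3 2270.1 in monocyte-like cells and Axl, a receptor for dying cells, 413 in fibroblast-like cells. Spp1 peaked in macrophage-like cells (143 CPM), where a single cell held 40.6% of its UMIs.

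Fibroblast-like cells carried most collagen transcripts. In them Col3a1 stood at 1828 CPM (1816 to 1839), Bgn at 1326, Fbn1 at 929.7, Col1a2 at 882, Col1a1 at 489, Col6a1 at 417, the cross-linking enzyme Loxl1 at 413 and Col14a1 at 362 CPM, each the highest of all classes. The sum of the fibrillar matrix list was nevertheless level between Schwann-like (10384 CPM) and fibroblast-like cells (10376 CPM), because Sparc, a collagen-binding protein, made up 67.4% of it in Schwann-like cells (6995 CPM). In these Col3a1 followed at 883, Col1a2 at 502 and Col5a2 at 371 CPM. With cells weighted equally, with doublets kept or with cells thinned, fibroblast-like cells led. Of the 14 members that peaked outside Schwann-like cells, Fn1 was highest in macrophage-like cells (1476 CPM) and elastin (Eln) in epicardial-like cells (331 CPM). Cluster 29 held 86.9% of the macrophage Fn1 UMIs, and without it monocyte-like cells had the most (1279 CPM, against 234 CPM). The matrix protease list was highest in fibroblast-like cells (3325 CPM), through the inhibitors Timp2 (948) and Timp3 (758) and the proteases Adamts5 (667) and Mmp2 (386 CPM). Timp2 peaked in epicardial-like cells (1608 CPM), Timp3 in lymphatic-like cells (1585 CPM), Timp4 in capillary-like cells (259.6 CPM), Mmp8 in neutrophil-like cells (482 CPM), and Mmp12 and Mmp13 in macrophage-like cells (50.5 and 34.3 CPM).

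The sum of the markers of activated fibroblasts was not highest in fibroblast-like cells (674 CPM). An unnamed cluster of 225 cells, with Postn among its leading genes, did not enter this comparison. Among the named classes the activation list was highest in pericyte-like cells (1093 CPM, 1.02 times Schwann-like cells), with Postn at 434, Fap at 234, Itgb5 at 229.7 and Ccn2 at 161 CPM. Cluster 29 alone held this list at 1864 CPM. Of 14 members 12 peaked elsewhere, among them Runx1 in NK cell-like cells (669.9 CPM), Thbs1 in monocyte-like cells (430.1 CPM), Comp in endocardial-like cells (201 CPM) and Cilp in fibroblast-like cells (23.4 CPM). Tnc and Ltbp2 rested on 6 UMIs each in their highest class and Thbs4 on 22. The TGF-beta list differed little between lymphatic-like cells (1832 CPM) and macrophage-like cells (1815 CPM, and 1630.0 CPM without cluster 29, below the 1671 CPM of endocardial-like cells). Cluster 29 alone held it at 2686 CPM. In lymphatic-like cells the receptors Tgfbr2 and Tgfbr3 stood at 559 and 292 CPM, Smad4 at 156 and Ski at 126. The ligand Tgfb1 peaked in monocyte-like cells (339 CPM), its receptor Tgfbr1 in non-classical monocyte-like cells (283 CPM), the inhibitor Smad7 and the latency protein Ltbp1 in endocardial-like cells (239 and 344 CPM), among 11 members highest elsewhere.

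Genes of glycolysis and trained immunity, the term for a lasting change of innate cells after a first stimulus, were highest in neutrophil-like cells (4039.7 CPM, 1.92 times monocyte-like cells). Acod1, which makes itaconate, gave 39.2% of this (1584 CPM), followed by Pkm (477), the lactate exporter Slc16a3 (442) and the histone demethylase Kdm6b (434 CPM). Of 12 members that peaked elsewhere, Aldoa (483 CPM) and Hk1 (90.4 CPM) were highest in pericyte-like cells, Ldha (422 CPM) in ILC2-like cells, Eno1 (189 CPM), Pgk1 (161 CPM) and Hk2 (116 CPM) in monocyte-like cells and Acly (74.9 CPM) in macrophage-like cells. Without cluster 29 Acly was at 39.99 CPM there and highest in capillary-like cells (66.3 CPM). Checkpoint and regulatory genes were highest in non-classical monocyte-like cells (3650.0 CPM, 1.62 times neutrophil-like cells). There Nr4a1, a factor needed by these cells, reached 787 CPM, the anti-phagocytic ligand Cd47 588, its receptor Sirpa 519 and Il10ra 362 CPM, and Cd274 (285), Havcr2 (253) and Il10 (228) peaked there too. Arg1 was highest in ILC2-like cells (281 CPM) and Vsir and Socs3 in neutrophil-like cells (203 and 222 CPM).

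Among classes, endothelial activation genes were highest in arterial-like cells (2960.1 CPM, 1.15 times capillary-like cells), led by the flow-responsive factor Klf2 (703), Esam (475), Jam2 (431) and Icam2 (392 CPM). Cluster 29 alone held the list at 3952 CPM. The inducible selectins were rare, with Sele highest in pericyte-like cells (52.6 CPM) and Selp in macrophage-like cells (94.9 CPM), where cluster 29 held 99.7% of its UMIs. Without that cluster Selp was highest in neutrophil-like cells (53.0 CPM). Klf2 peaked in macrophage-like cells (1200.3 CPM) and Plvap in endocardial-like cells (443 CPM), and without cluster 29 Klf2 was level between neutrophil-like (982 CPM) and macrophage-like cells (976 CPM). Receptors for sympathetic and hormonal signals were highest in pericyte-like cells (1113 CPM), with the glucocorticoid receptor Nr3c1 at 428, the endothelin receptors Ednra and Ednrb at 402 and 169, and the angiotensin receptor Agtr1a at 93.2 CPM. Of the adrenergic receptors named here, Adrb1 peaked in non-classical monocyte-like cells (59.7 CPM) and Adra1a in fibroblast-like cells (2.97 CPM), while Adra2a had 1 UMI in its highest class. Early response genes that digestion can induce were highest in neutrophil-like cells (13589 CPM), ahead of ILC2-like (10028 CPM) and macrophage-like cells (9342 CPM), led by Junb (3703), Dusp1 (3163), Fos (3031) and Egr1 (1146 CPM). Among classes, the IL-1 and NF-kB lists were thus highest where these were highest, while cluster 29 held early response genes at 12917 CPM. Among the named classes, cell cycle genes were highest in NK cell-like cells (982 CPM, and 182 to 1358 over libraries). Stmn1 stood there at 232, Mki67 at 208, Top2a at 200.0 and Pcna at 101 CPM. Unnamed clusters of 141, 37 and 19 cells, with Mki67 and Top2a among their leading genes, did not enter this comparison. The sex-linked list was highest in pericyte-like cells (667 CPM), where Xist gave 91.4%, and stood at 350.5 CPM in macrophage-like cells. Library 3, with 648 of the 1229 macrophage-like cells, had Xist at 0.0675 CPM from 2 UMIs, so that pooled levels depend on how many cells of a class it gave. Within libraries 1 to 4 the list was at 698, 650.1, 368 and 837 CPM in pericyte-like and at 535, 469, 218 and 453 CPM in macrophage-like cells.

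Further listed genes are given here by the cell type in which they peaked. For Mmp19 (17 UMIs), Ccnb2 (16 UMIs), Mmp11, Tgfb3, Hif1a, Ski, Ier2 and Junb, the interval at the peak also held the level in the class leading their list. Non-classical monocyte-like cells had the most Itgam (503 CPM), an integrin of myeloid cells, Klf4 (495 CPM), Tnfrsf1b (395 CPM), Irak3 (252 CPM), Smad3, Adam17 and Casp1. Monocyte-like cells had the most Tgfbi (479 CPM), Mmp19 and Ccnb2, and neutrophil-like cells the most Zfp36 (711 CPM). In ILC2-like cells Junb (3827 CPM), Jund (2008 CPM), Nfkbia (1764 CPM), Nr3c1 (841 CPM), Fosb and Ier2 peaked, and in macrophage-like cells Jun (1130.5 CPM), Atf3 (653 CPM), Il10rb, Ccl8 and the heat shock genes Dnajb1, Hspa1a and Hspa1b, of which Dnajb1 was higher in NK cell-like cells (48.0 against 45.8 CPM) without cluster 29. Dendritic-like cells had the most Pfkp (223 CPM), Relb and Mtor, and NK cell-like cells the most Ccl3 (214 CPM). Among vascular cells, Nos3 (176 CPM), which makes nitric oxide, Ednrb (469.8 CPM) and Cthrc1 peaked in endocardial-like cells, Adamts1 (199 CPM), Lgals9, Usp18 and Il18bp in arterial-like cells, the natriuretic peptide receptor Npr1 (81.3 CPM) and Jam2 (539 CPM) in capillary-like cells, and Stab1 (450.0 CPM), Thbd, Meox1, Hif1a, Ddah1 and Tyms in lymphatic-like cells. Mmp11 peaked in pericyte-like and Pfkl in smooth muscle-like cells. Fibroblast-like cells had the most Col5a1 (231 CPM), Col6a3 (224 CPM), Loxl2 and Chrna7, epicardial-like cells the most Hsp90aa1 (392 CPM), Mmp23 (216 CPM), Setd7, Tgfb3 and Lox, and Schwann-like cells the most Tgfb2 (177 CPM), Ccn2 (217 CPM), Ski, Timp1 and Gpnmb. The Y-linked genes had 8794 UMIs in library 3 and 9, 6 and 27 in libraries 1, 2 and 4. Within library 3 Ddx3y (331 CPM, 42 UMIs) and Uty (149.6 CPM, 19 UMIs) were highest in ILC2-like, Eif2s3y (154 CPM, 15 UMIs) in lymphatic-like and Kdm5d (44.9 CPM, 14 UMIs) in NK cell-like cells.

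The genes named for every class in advance separated inflammatory from structural cells. Il1b (chromosome 2, 129364570 to 129371139, minus strand) was at 11731 CPM (11537 to 11927) in neutrophil-like cells and at 1251, 709, 456 and 159.8 CPM in non-classical monocyte-like, monocyte-like, dendritic-like and macrophage-like cells, against 1.33 CPM in fibroblast-like cells. Over the libraries it ranged from 7144 to 13150.0 CPM in neutrophil-like cells. Ccr2 (chromosome 9, 124101950 to 124113557, plus strand), the receptor that draws monocytes from the bone marrow, was highest in monocyte-like cells at 613 CPM (564 to 666). ILC2-like cells had 363, dendritic-like cells 159.7, NK cell-like cells 128, macrophage-like cells 99.4 and non-classical monocyte-like cells 12.9 CPM. Mmp9 (chromosome 2, 164940780 to 164955850, plus strand), a gelatinase, was at 786 CPM (736 to 838) in neutrophil-like cells and at 6.63 CPM in macrophage-like cells. Col1a1 (chromosome 11, 94936224 to 94953042, plus strand) fell from 489 CPM in fibroblast-like to 221 in Schwann-like and 136 in epicardial-like cells. Col3a1 (chromosome 1, 45311538 to 45349706, plus strand) was nearly as high in epicardial-like (1590.0 CPM) as in fibroblast-like cells (1828 CPM). Postn (chromosome 3, 54361109 to 54391037, plus strand) encodes a matrix protein of healing tissue. Among the named classes it was highest in Schwann-like (686 CPM, 595 to 786), pericyte-like (434 CPM) and endocardial-like cells (317 CPM), with 52.2 CPM in fibroblast-like cells.

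The tdTomato reporter (tdtomato among the features) is switched on by the inducible Cre in cells that use the Ccr2 promoter while Cre is active, and stays on in their progeny. Its RNA was highest in non-classical monocyte-like cells at 569 CPM (536 to 603). It was seen in 83.1% of these cells (median 4900 UMIs per cell), against 8.91% of fibroblast-like cells (median 6422 UMIs), which lack Ccr2 (0.0934 CPM) and had tdTomato at 15.6 CPM. ILC2-like, monocyte-like and dendritic-like cells followed at 378, 365 and 309 CPM, and NK cell-like, neutrophil-like, macrophage-like and T cell-like cells at 135, 96.7, 91.2 and 88.7 CPM. B cell-like cells (16.0 CPM) lay at the level of fibroblast-like cells. The share of macrophage-like cells with a tdTomato UMI was 18.1%.

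**Figure D2:**
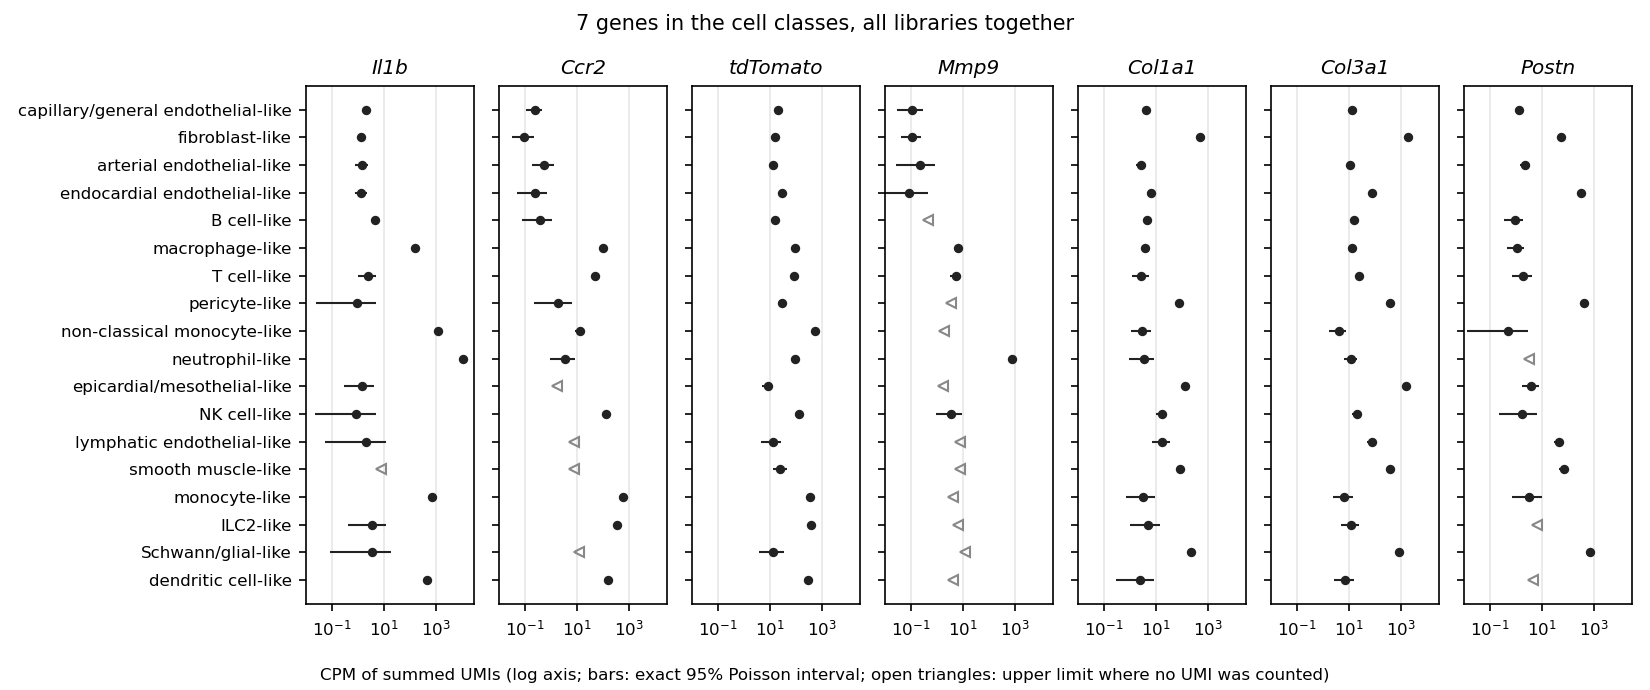
CPM of summed UMIs (log axis) of 7 genes in the 18 cell classes over all libraries; points are values, bars exact 95% Poisson intervals and open triangles the upper limit where no UMI was counted. Il1b reaches 11731 CPM in neutrophil-like cells, Ccr2 613 CPM in monocyte-like cells and Col3a1 1828 CPM in fibroblast-like cells.

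Long-lived resident macrophages of the heart express Lyve1, Timd4 and Folr2, while cells that arrived as monocytes are known for Ccr2. The macrophage-like cells high in the 3 resident genes (228 cells, median 6244 UMIs) were therefore set against the remaining macrophages of the same cluster (691 cells, median 4793 UMIs). Of the latter, 291 lay in 2 sub-clusters led by haemoglobin genes, 1 of them also by the cardiomyocyte genes Myl2 and Tnnt2, and 2 cells held 99.4% of the haemoglobin UMIs there. The Lyve1-high cells had less MHC class II, less of the inflammatory cytokine Il1b and less Ccr2, and more of the coagulation factor F13a1, the scavenger receptor Cd163 and the endothelin receptor Ednrb. Of 156 listed genes with at least 50 UMIs, 9 met the size rule as higher in Lyve1-high cells and 36 as lower. The design set no test where cells are not tied to samples, and none was run for this contrast within libraries either. A call rests on size over all cells and within each of the 4 libraries. In libraries 1 to 4 the Lyve1-high side had 42, 46, 126 and 14 cells and the Lyve1-low side 85, 109, 416 and 81. For genes without UMIs on the Lyve1-high side, such as Cxcl9 and Itgax, any UMI on the other side meets the bound within a library.

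Among the higher genes were 5 of the 9 resident macrophage genes that did not define the sides. F13a1 was 4.27-fold higher (4.10 to 4.45), Cd163 3.16-fold, Gas6 2.79-fold, Cbr2 2.79-fold and the antibody receptor Fcgrt 2.10-fold. Ednrb, which clears and senses endothelin, was 43.0-fold higher (22.8 to 91.1) at 127 against 2.95 CPM. The complement gene C4b was 3.45-fold higher, and the chemokines Ccl6 and Ccl9 were 2.79-fold and 2.66-fold higher.

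MHC class II was the list with the largest share of members lower, 6 of 7, and its sum was 5.12-fold lower. H2-Eb1 was 6.71-fold lower (6.29 to 7.16), H2-Aa 5.75-fold, H2-Ab1 5.59-fold and Cd74 4.57-fold (4.42 to 4.73). Of 10 IL-1 and inflammasome genes 2 were lower, with Il1b 33.3-fold lower (18.0 to 69.8) at 6.88 against 229 CPM, and of 12 TNF and NF-kB genes 5 were lower, with Cxcl2 4.04-fold lower. From the recruitment list 4 of 12 genes were lower, among them Ccl4 (9.81-fold) and Ccr2 (2.78-fold, 2.05 to 3.86), while 2 were higher. Cxcl9 had 0 UMIs against 70 and Itgax 0 against 51, which makes them at least 9.99-fold and 7.28-fold lower over the pooled cells. The proteases and matrix genes Mmp12 (39.0-fold, 10.6 to 324) and Col14a1 (5.04-fold), the osteopontin gene Spp1 (79.2-fold, 14.0 to 3147), the junction gene F11r (6.61-fold), and Smad7 (6.85-fold) and Skil (3.90-fold), which restrain TGF-beta signalling, were lower as well. Single cells held 41.4% of the Cxcl9 and 40.5% of the Spp1 UMIs of the Lyve1-low side. Of early response genes 5 of 13 were lower, such as Atf3 (2.53-fold) and Fos (2.20-fold). All 5 turned higher in Lyve1-high cells once sub-clusters high in Fos were left out, as given below. Of 11 TGF-beta genes 3, of 13 efferocytosis and complement genes 3 and of 10 checkpoint genes 2 were lower. The lists without a call were fibroblast activation and sex-linked genes, and 1 gene was lower in each of the interferon, protease, matrix, glycolysis, endothelial and cell cycle lists. The tdTomato level was 18.6 against 67.2 CPM, and it did not meet the rule because the sides were level in library 2 (ratio 0.994).

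The Lyve1-low side held 300 cells in sub-clusters high in Fos. Without these, 12 genes were lower and 11 of them were among the 36. All 6 MHC class II genes, Il1b (8.27-fold) and Mmp12 (22.4-fold) were still lower and all 9 higher genes were still higher, whereas 25 calls were lost. Of these, 14 genes were no longer at least 2-fold lower over all cells. Skil stayed lower (1.81-fold), while 12 of the 14 turned higher, among them Cxcl2 (1.76 times the Lyve1-low level) and all 5 called early response genes. Egr1, Icam1, Ier2 and Zfp36 turned by more than 2-fold. Leaving out these cells takes away early response transcripts by construction. Another 6 genes missed the rule in a library at 2-fold or more over all cells, among them Spp1 (137-fold, 24.2 to 5435), F11r (5.91-fold), Col14a1 (5.17-fold), Ccl4 (3.01-fold) and Ccr2 (2.60-fold), and 5 had under 50 UMIs, among them Smad7 (4.78-fold, 1.38 to 25.5), Cxcl9 and Itgax. Without the 291 cells in sub-clusters led by haemoglobin genes 38 genes were lower, 30 of them among the 36, and Cxcl9, Itgax, Smad7 and Spp1 missed the rule. The calls of Itgax and Smad7 were lost when any 1 library was left out, with 51 UMIs each in all, Cxcl9 was lost without library 2, Fcgrt without library 3. With cells thinned to 1000 UMIs 21 genes were lower, and Ednrb, C4b, Gas6, Fcgrt, Cxcl9, Spp1, F11r and Col14a1 missed the rule. At Leiden resolution 2, 19 genes were lower, Gas6, Fcgrt, Cxcl2 and Ccr2 missed it and Spp1 turned, and Ccr2 and Spp1 also missed it with doublets kept.

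**Figure D3:**
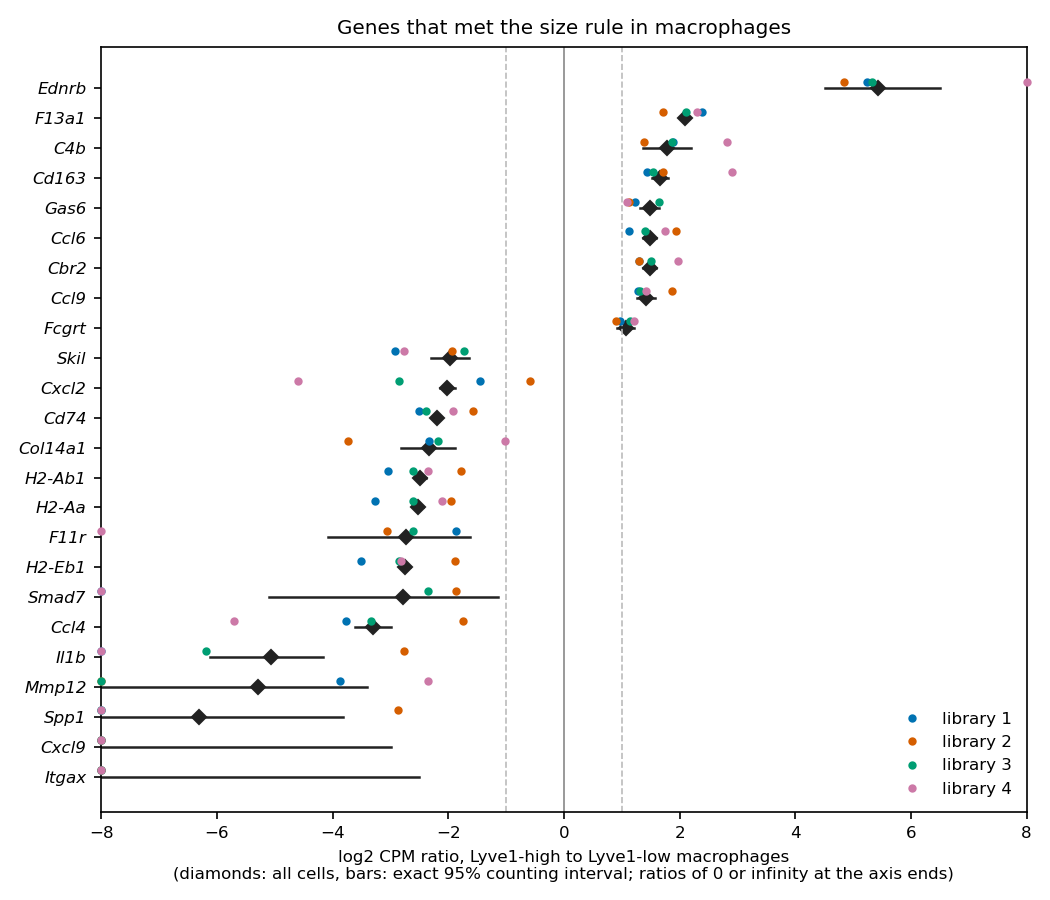
Log2 CPM ratio of Lyve1-high (228 cells) to Lyve1-low (691 cells) macrophages for the 9 higher and the 15 lowest genes; diamonds are all cells, bars exact 95% counting intervals and coloured points the 4 libraries, with ratios of 0 or infinity at the axis ends. Ednrb lies farthest to the right at 5.42 and Spp1, among genes with a UMI on both sides, farthest to the left at -6.31.

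Last, the spread of the functional lists between the 4 libraries was measured within 3 main populations. In fibroblast-like cells the fibrillar matrix list lay between 9117 and 11322 CPM (median 10601). Col1a1 ranged from 418 to 558 CPM, with the highest library 1.34 times the lowest, and Col3a1 from 1545 to 2199 CPM (1.42 times). Postn lay between 47.1 and 62.3 CPM. Early response genes ranged from 2979 to 4234 CPM in fibroblast-like cells and from 1201 to 1690.3 CPM in endothelial-like cells. The interferon list ranged from 1461 to 2104 CPM in endothelial-like cells (median 1797). MHC class II was low there and spread more, from 63.7 to 201 CPM. Postn was at 80.7, 54.8, 36.9 and 102 CPM over all endothelial-like cells of libraries 1 to 4, where endocardial-like cells made up 8.40%, 5.64%, 5.23% and 11.6% of all cells. Within endocardial-like cells Postn ranged from 283 to 339 CPM, and capillary-like cells had 1.32 CPM.

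In macrophage-like cells the fibrillar matrix list stood at 409, 3776, 367 and 3313 CPM in libraries 1 to 4, the TNF and NF-kB list at 4017, 9731, 3788 and 7231 CPM, and the MHC class II list at 19331, 10502, 17317 and 18597 CPM. Cluster 29, with 76 of its 112 cells from library 2 and 34 from library 4, held Fn1 at 7331 CPM. Without it the fibrillar matrix list was at 409, 700.4, 324 and 750.4 CPM, the TNF and NF-kB list at 4017, 4146, 3728 and 4026 CPM and the MHC class II list at 19331, 19135.5, 17442 and 29122 CPM. Ccr2 in macrophage-like cells was at 212, 29.9, 112 and 107 CPM, Il1b at 277, 176, 109 and 225 CPM, and tdTomato at 135, 113, 62.3 and 119 CPM. These cells include the cluster of 54 cells high in Ccr2, with 13, 11, 19 and 11 cells in libraries 1 to 4. Without cluster 29 Ccr2 was at 212, 37.5, 113 and 146 CPM, Il1b at 277, 241, 109.7 and 336 CPM, which made library 4 the highest in place of library 1, and tdTomato at 135, 74.0, 62.8 and 122 CPM. These values describe the libraries and set none of them in a group.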

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

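The values in this part lie outside the comparisons of the report and were not planned. The Y-linked and haemoglobin levels are given because each lies above the limit that a count of 0 allows. The 4 Y-linked genes of the sex-linked list stood at 0.221, 0.143, 297 and 0.791 CPM in libraries 1 to 4, from 9, 6, 8794 and 27 UMIs. Xist, transcribed from the inactive X chromosome, stood at 575, 592, 0.0675 and 531 CPM in the same libraries, the value of library 3 from 2 UMIs. Library 3 thus had the sex-linked RNA of male cells and libraries 1, 2 and 4 that of female cells, though the labels used here give no sex. Library 3 also had the lowest fibroblast-like and the highest macrophage-like and endothelial-like share. Sex was not separated from other differences between libraries. Haemoglobin genes took 32.6%, 14.8%, 65.2% and 20.2% of the UMIs of barcodes that failed the cell filter in libraries 1 to 4, against 0.0127%, 0.0976%, 0.319% and 0.00712% in barcodes that passed it. No explanation was tested for these values.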

How the results depend on the processing

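The alternatives without the sub-clusters high in Fos, without those with haemoglobin-loaded cells and without cluster 29 were chosen after the result was seen, as were the division of mixed clusters, the doublet threshold of library 3 and the choice of macrophage sub-clusters. The other alternatives were planned. Of 36 genes lower in Lyve1-high macrophages, 20 were among the 21 lower with cells thinned to 1000 UMIs, where 101 genes in place of 156 had 50 UMIs. At Leiden resolution 2, 18 of them were among 19 lower genes, and without the sub-clusters high in Fos 11 were among 12. In the other alternatives run for this comparison 31 to 42 genes were lower, with 30 of the 36 among the 38 without haemoglobin-loaded sub-clusters, and leaving out each library gave 33 to 37. The number of higher genes ranged from 6 to 10, and no gene was called in the opposite direction in any alternative run. Log2 ratios turned above 0 without the sub-clusters high in Fos for Atf3 (0.75), Cxcl2 (0.82), Egr1 (1.36), Fos (0.79), Icam1 (1.19), Ier2 (1.14), Junb (0.96), Nfkbia (0.61), Nlrp3 (0.14), Nr4a1 (0.69), Tnfaip3 (0.81) and Zfp36 (1.02). Leaving out these cells takes away early response transcripts by construction. Spp1 turned at Leiden resolution 2 (2.55), and the cause was not tested. The leading class was kept for 16 of 18 lists with cells weighted equally, 17 with doublets kept, 16 with cells thinned and 18 without cluster 29. No paired analysis was possible because stroke and control cells could not be tied to samples. The macrophage sides were compared within each library by ratio, without a test. For the same reason the planned fits of stroke against control were not run, namely other size factors, no filter on low counts, each sample left out, an estimated correlation between list genes, and doublets kept or other resolutions for shares between groups. With fewer UMIs, fewer genes reached the minimum of 50.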

Other observations

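The tests in this part on Lyve1-high macrophages, on the reporter and on doublets were chosen after the results were seen, and those on the serous cavity lists were written before their values were seen. The clusters named in this paragraph were chosen after their values were seen. A capillary-like sub-cluster of 312 cells, present in all libraries (60, 71, 86 and 95 cells), held the interferon-induced genes Isg15 at 1114 CPM (1024 to 1209) and Cxcl9 at 428 CPM (373 to 489). The main arterial-like cluster had Isg15 at 306 CPM and the largest capillary-like cluster Cxcl9 at 174 CPM. An unnamed cluster of 225 cells, 157 of them from library 1, had the most Postn of all clusters shown, at 1308 CPM (1249 to 1369). Among fibroblast-like cells, a cluster of 1026 cells had the chemokines Ccl2 at 204 CPM and Ccl7 at 141 CPM, and a cluster of 97 cells had Col3a1 at 3432 CPM and Col1a1 at 762 CPM. A macrophage-like cluster of 54 cells had Ccr2 at 543 CPM (483 to 607), near the level of monocyte-like cells.

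Lyve1-high macrophages had less MHC class II and less of many early response genes than the others, and digestion could have raised such genes in part of the Lyve1-low cells. Once the sub-clusters high in Fos were left out, all 6 MHC class II genes were still lower by the size rule. A stress response of the Lyve1-low side marked by high Fos, as the whole cause, does not allow this. Among the cells kept, a sub-cluster of 145 cells with Fos at 269 CPM had H2-Eb1 and Cd74 among its leading genes. A response to digestion without high Fos was not tested. Of 12 called genes of the IL-1, NF-kB and early response lists, 1 (Il1b) was still lower and 10 had ratios above 1. Whether those genes were raised in the heart or in the suspension cannot be told apart, since no label gives cells processed without digestion. No biological explanation was tested, as no group could be assigned to the cells.

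Non-classical monocyte-like cells had the most reporter RNA at little Ccr2, and free RNA taken into droplets might give such a signal. The ratio of reporter CPM in these cells to fibroblast-like cells was 34.9, 34.8, 23.6 and 44.4 in libraries 1 to 4. The lowest, 23.6, lies far above a ratio near 1 that free RNA would give, which counts against it. A hypothesis is that many of these cells descend from cells that once used the Ccr2 promoter and later lost its transcript. It was not tested here, and no source used here gives the time of labelling.

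Clusters 29 (macrophage-like) and 17 (B cell-like) came mostly from libraries 2 and 4, with 0, 76, 2 and 34 cells and 15, 292, 9 and 87 cells in libraries 1 to 4. A candidate explanation is that they are cells of the serous cavity type, carried along with the heart. Of 5 genes listed for macrophages of serous cavities, 5 were at least 2-fold above cluster 10, such as Garnl3 (37.1-fold, 29.3 to 47.4) and Itga6 (8.78-fold), and of 6 listed for B-1 cells, 6 were at least 2-fold above cluster 9, such as Zbtb32 (28.0-fold) and Bhlhe41 (6.12-fold). Their median UMIs per cell were high, 11618.5 and 8070. However, 58 genes of cluster 29, such as Saa3 (34.7-fold) and Selp (8.10-fold), lay at least 2-fold above the highest of all other clusters. So did 22 genes of cluster 17, such as Il5ra (4.64-fold). Of the listed genes, 2 of the 5 and 2 of the 6 lay above the highest other cluster. Doublets of cells with the mean profiles of other clusters, as the whole cause, do not allow this. Doublets of 2 cells of the same cluster stay open, as do doublets with rare cells that differ from the mean of their cluster. Whether the tissue taken or the animals differed between libraries was not tested.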
